A study of Priestia megaterium with 8 samples.

How the data were processed

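Transcript levels were measured in Bacillus megaterium DSM319 (now also named Priestia megaterium) with custom Agilent arrays that carry up to 3 probes per open reading frame, per the series' design text. Each of the 8 arrays held RNA of a strain without its own degS and degU genes that expressed degU from a xylose-inducible plasmid, labelled with Cy3, and RNA of an empty vector control strain, labelled with Cy5, per the labels. Cells were grown in LB medium at 37 °C and 170 rpm and induced at an optical density (546 nm) of 0.5 with 0.25 % xylose, per the labels' protocols. Cells were treated with sodium azide and broken mechanically, and RNA was purified on columns and labelled chemically, per the labels' protocols. The labels name 2 different plasmids for the control strain (pMM1520 in the labelling protocol, pMM1522 in the sample source), and which of them was used stayed unresolved.

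The authors deposited scanner output with a linear intensity per spot and channel, made with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The authors' deposited gene tables hold log2 ratios, summarised over the probes of a gene, and p-values, made with limma in a version not given in the sources used here. The design text states 3 to 5 biological replicates per group and the authors' own rule, a p-value under 0.01 at every probe and an absolute log2 ratio above 1. The background correction and normalization behind the authors' p-values and log2 ratios are not given in the sources used here.

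From the intensities, background was corrected in limma 3.58.1 (R 4.3.3) by normexp with an offset of 50 on the mean signal and the local background. Log2 ratios of Cy3 over Cy5, the degU strain over the control, were normalized within each array by loess, with control spots at weight 0. Spots marked as uneven or as outliers by the scanner software were left out. Probes were averaged per locus tag as the arrays' annotation names it. The arrays carried 15027 gene probes for 5124 genes, of which 4817 had 3 probes, 269 had 2 and 38 had 1. 4 gene probes had a repeated sequence. A symbol was given for 1778 genes, and the others are named by locus tag. A gene was tested if at least 1 of its probes was well above background in either channel on at least 3 arrays, which left 4620 genes. 18 probes of sequences from outside the genome annotation were left out of the tests.

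All 8 arrays entered a single limma fit (lmFit and eBayes) with a mean per growth phase, so that both phases shared an estimate of the spread. The degU effect in each phase was tested against 0, and the difference between phases was tested as stationary minus exponential. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 value above 1, two-sided. Growth phase changes within each strain were tested on the log2 values of a single channel after loess and quantile normalization of the average signal between arrays (Aquantile). All p-values for single genes are limma's. Values are means ± SD over the arrays of a phase for the degU effect, and means with limma's standard error (SE) for differences between phases.

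A gene whose probes were all not well above background in a group has only a bound there. Such genes are given as at least N-fold higher or lower, with the brighter group's mean set against the dimmer group's mean of, per array, the higher of the lowest well-detected signal and the gene's own signal. These bounds use single channels after loess and Aquantile and remain open to dye bias. Dyes were not swapped on any array, so a bias of a gene's label is part of each ratio between the strains. A bias equal in both phases cancels in the difference between phases and in the growth phase changes.

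28 gene lists were fixed before the data were examined and matched by symbol: DegU targets known from Bacillus subtilis, extracellular proteases and hydrolases, flagella, chemotaxis, competence and DNA uptake, sporulation, biofilm matrix and capsule, sigma-B general stress, heat shock and protein quality control, secretion machinery, cell wall autolysis, ribosomal proteins, ATP synthase and respiration, TCA cycle and glyoxylate, glycolysis and gluconeogenesis, xylose and pentose use, carbohydrate uptake and use, acetoin and acetate, branched-chain amino acid synthesis, histidine, tryptophan and arginine synthesis, purine and pyrimidine synthesis, nitrogen and peptide use, phosphate starvation, iron uptake, polyhydroxyalkanoate granules, cobalamin synthesis, gas vesicles, and SOS response and prophage. The cobalamin synthesis list also held all symbols that begin with cys, for cysteine and sulfate metabolism, and the symbols hemA, hemB, hemC, hemD and hemL. Its counts are therefore not those of cobalamin synthesis alone. Each list was tested with limma's camera at an inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over all lists with at least 4 tested members. Camera with an estimated correlation and fry were run as alternatives. Fry asks whether a list's genes move on balance in a single direction, not whether they differ from other genes.

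Genes to be named were fixed by a rule before the data were examined: degU and degS, the 12 highest and the 12 lowest called genes with the same direction on every array of a phase, and up to 4 called members of each list. For the difference and the growth phase changes the rule took the 6 highest and 6 lowest called genes, without the condition on every array. Of these, genes described only as hypothetical were left out, as the rule allowed. After the values were seen, the text was narrowed to up to 2 members of lists past the threshold, up to 4 of the DegU target and exoenzyme lists, 1 of each other list in the strain comparisons, and the flagellin gene hag. Other members of small counts are named as such and were chosen after their values were seen.

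The tests of genes were checked on simulated log2 ratios and single-channel values for 4620 genes, in which 100 genes were changed by 1.5 and 100 by 3 on the log2 scale. For the exponential comparison 97 % and 99 % of the changed genes were recovered, for the stationary comparison 97 % and 100 %, and for the difference 94 % and 100 %. For growth phase in the vector control 98 % and 100 % were recovered, and in the degU strain 98 % and 98 %. Of 4420 unchanged genes, 0, 1, 0, 0 and 2 were called in these comparisons.

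Alternatives were no background correction, normexp with an offset of 0, Feature Extraction's own processed signals, median centring in place of loess, scale normalization between arrays, filters on dim probes, the median over probes, uneven spots kept, a fit on the arrays of a single phase, other variance models and array weights, the array's position on the slide as a block, other thresholds, the replicate number as a block, and leaving out each array in turn. 2 alternatives were added after the data were seen: stationary replicates 1 to 3 alone, and near-identical control channels averaged. No genome sequence or gene coordinates were used here, so positions of genes are not given.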

Results

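The data describe how gene expression changed in B. megaterium when the response regulator DegU was expressed without its sensor kinase DegS. In B. subtilis, DegU controls genes for secreted enzymes, motility, competence and biofilm formation. 3 arrays compared the degU strain with the empty vector control in exponential phase and 5 in stationary phase. Median signals per array were 532 to 610 in Cy3, the degU strain, and 559 to 1132 in Cy5, the control, against negative control probes at 384 to 589 and 252 to 424. Cy3 signals were well above background for 49.9 % to 51.9 % of probes in exponential phase and for 23.9 % to 40.5 % in stationary phase. In Cy5 these shares were 79.7 % to 82.4 % and 66.1 % to 74.6 %. Log2 ratios correlated across genes at r = 0.94 to 0.98 between exponential arrays, 0.91 to 0.97 between stationary arrays and 0.39 to 0.52 across phases. The number of arrays limits the precision.

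The control channels of stationary replicates 1 and 5 were near identical, as were those of replicates 2 and 4. Their log2 values differed with an SD of 0.12 and by over 2-fold for 0 of the 2310 brighter genes, while other pairs of stationary control channels had SDs of 0.23 to 0.58. Whether these arrays held the same control RNA is not given in the sources used here. If they did, p-values of the stationary phase measure a partly technical spread.

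Expression of degU itself was checked on every array. Its log2 ratio was 10.28, 10 and 10.08 on the exponential arrays and 10.53, 11.17, 10.66, 11.19 and 10.10 on the stationary arrays. The mean was 10.12 ± 0.15 (SD, n = 3; adjusted p = 1.5e-09) in exponential and 10.73 ± 0.46 (SD, n = 5; adjusted p = 6.02e-11) in stationary phase. These values did not differ between phases past the threshold (difference 0.61, SE 0.24, adjusted p = 0.0504). One of the 3 degU probes gave control signals of 3022, 2280 and 3615 in exponential phase, against 557 to 1034 for the other probes. The degS probes were not well above background in the degU strain, and in the control 1 of the 3 probes was so on 3 of the 8 arrays, so the ratio compares mostly background. The gene was not called (0.42 ± 0.21, n = 3, and 0.52 ± 0.14, n = 5).

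The exponential comparison asked which transcripts differ during growth when degU is expressed. The largest increase after degU was in BMD_3801, a cell wall hydrolase gene, with a log2 ratio of 7.53 ± 0.23 (SD, n = 3; adjusted p = 2.48e-08). Next came BMD_2936, which encodes a putative membrane protein (6.06 ± 0.37), BMD_0195, which encodes an SH3 domain protein (5.58 ± 0.10), the drug transporter gene BMD_0917 (4.92 ± 0.08) and the FMN reductase gene BMD_0918 (4.36 ± 0.24). 3 capsule genes stood beside them, with capA (BMD_1005) at 4.34 ± 0.27, capC (BMD_1004) at 4.28 ± 0.30 and capB (BMD_1003) at least 19.9-fold higher. At the other end, genes for the synthesis of purine nucleotides and gabT, a 4-aminobutyrate transaminase gene (-4.33 ± 0.86), were lowest, and the regulator gene BMD_2264 was at least 10.9-fold lower. Of 4620 genes tested, 1259 were called, 596 higher and 663 lower in the degU strain, and 160 of them have only a bound. Without background correction the balance turned, with 496 higher and 478 lower.

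In the list of purine and pyrimidine synthesis, 16 of 28 genes were lower, 1 (pyrH) was higher and 11 were not called (adjusted p = 0.00194; adjusted p = 0.573 with an estimated correlation). The log2 ratio of purM was -4.89 ± 2.88 (SD, n = 3), that of purN -4.82 ± 2.82, of purS -4.46 ± 1.91, of purK -4.40 ± 1.06 and of purE -3.88 ± 0.74. Values for purH, purD, purF and purC were -4.31, -4.30, -4.25 and -4.05. The spread came mainly from exponential replicate 3, where purM stood at -1.58, against -6.29 and -6.80 on replicates 1 and 2. Without replicate 3, purM, purN, purH, purD, purF, purS and purC stood at -6.55, -6.44, -5.81, -5.75, -5.66, -5.53 and -4.85, and 17 genes of the list were lower (adjusted p = 3.82e-06). Without replicate 2 the same genes stood at -3.94, -3.92, -3.52, -3.57, -3.48, -3.70 and -3.44. Without replicate 1, purM, purN, purH, purD and purF stood at -4.19, -4.09, -3.60, -3.59 and -3.61.

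Genes of motility and of aerobic energy metabolism were lower in the degU strain in exponential phase. Of 34 flagellar genes, 18 were lower, 0 were higher and 16 were not called (adjusted p = 2.86e-06; adjusted p = 0.519 with an estimated correlation). The motor genes motA and fliM were at least 3.58-fold and at least 3.1-fold lower, and hag, which encodes flagellin, had a log2 ratio of -1.92 ± 0.48. In chemotaxis, cheR was higher (2.35 ± 0.29), cheV was lower and 5 genes were not called (adjusted p = 0.23). Of 35 genes for ATP synthase and respiration, 16 were lower, 1 (cccB) was higher and 18 were not called (adjusted p = 7.02e-05; adjusted p = 0.519 with an estimated correlation). The lower members lay in cytochrome oxidases, the cytochrome bc complex and succinate dehydrogenase, with ctaE at -2.95 ± 0.34 and ctaC at -2.87 ± 0.29. Of 16 genes of the TCA cycle, 12 were lower, 1 (fumC) was higher and 3 were not called (adjusted p = 0.00249; adjusted p = 0.519 with an estimated correlation). Among them, odhB of the 2-oxoglutarate dehydrogenase stood at -2.91 ± 0.29 and icd, isocitrate dehydrogenase, at -2.68 ± 0.22.

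Biosynthetic lists were lower as well. In branched-chain amino acid synthesis, 8 of 10 genes were lower and 2 were not called (adjusted p = 0.000511; adjusted p = 0.519 with an estimated correlation). The aminotransferase gene ilvK stood at -2.43 ± 0.20, and ilvD was at least 4.46-fold lower. In the cobalamin list, 18 of 37 genes were lower, 3 (cbiO1, cbiO2 and cbiQ, cobalt transport) were higher and 16 were not called (adjusted p = 7.49e-05; adjusted p = 0.519 with an estimated correlation). Its largest changes were in genes of cysteine and sulfate metabolism, cysK (-3.49 ± 0.34) and cysC (-2.04 ± 0.63). In the iron list, 7 of 13 genes were lower, 1 (fur) was higher and 5 were not called (adjusted p = 0.00194; adjusted p = 0.519 with an estimated correlation). Of the lower members, sufB, sufC, sufD and sufS assemble iron-sulfur clusters rather than take up iron, with sufD at -2.76 ± 0.15 and sufS at -2.70 ± 0.10.

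Gas vesicle, ribosomal protein and sporulation lists were higher. Of 14 gas vesicle genes, 8 were higher and 6 were not called (adjusted p = 7.87e-05; adjusted p = 0.519 with an estimated correlation), with gvpP at 1.44 ± 0.22 and gvpA at 1.42 ± 0.21. The count was 2 without background correction and 14 with processed signals. Of 54 ribosomal protein genes, 7 were higher, 2 (rpsA and rplI) were lower and 45 were not called (adjusted p = 0.0071; adjusted p = 0.693 with an estimated correlation). The ratio of rpsB was 1.61 ± 0.13 and that of rpsA -1.53 ± 0.18. With median centring in place of loess, 1 ribosomal gene was higher, 4 were lower and the list was not past the threshold (median 0.06, adjusted p = 0.559). In sporulation, 12 of 74 genes were higher, 5 (spoVG, spoVS, sigF, spoIIAB and spo0F) were lower and 57 were not called (adjusted p = 0.0263; adjusted p = 0.573 with an estimated correlation), against 8 higher and 10 lower with median centring. Its largest changes were in sleB (BMD_3220), a spore cortex lytic enzyme gene (3.84 ± 0.10), and spo0M (BMD_4015, 3.03 ± 0.23). Of the 108 genes in this list, 74 passed the filter on dim probes, with a median log2 ratio of 0.254. Foreign probes without signal above background had mean log2 ratios of 0.29 to 0.84. Whether such an upward lean adds to the sporulation list was not tested.

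Genes with the symbols of known DegU targets went both ways in exponential phase. Of 14 genes in that list, 7 were higher, 4 were lower and 3 were not called (adjusted p = 0.36). The lower ones were nprM, a neutral protease gene at least 2.33-fold lower, and the other copies of capA, capB and capC (BMD_1094, BMD_1092 and BMD_1093), of which capC was at least 5.28-fold lower (adjusted p = 1.59e-06). Of 17 genes for extracellular proteases and hydrolases, 4 were higher (wprA, ywaD, sacB and vpr), 3 were lower (ggt of BMD_1095, nprM and lipA) and 10 were not called (adjusted p = 0.23). The ratio of ywaD was 3.12 ± 0.35 and that of wprA, a cell wall protease gene, 2.49 ± 0.12, while ggt was at least 5.02-fold lower. The symbol pgsA, matched among the higher targets, belongs here to a phosphatidylglycerophosphate synthase rather than to a capsule protein.

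10 of 28 lists passed the threshold in exponential phase, 0 with an estimated correlation and 25 with fry. Adjusted over the list alone, the counts of these lists were the same. Median centring in place of loess moved the median of all genes from 0 to -0.161 and the calls to 380 higher and 1163 lower. 14 probes of foreign sequences without signal above background in either channel had mean log2 ratios of 0.29 to 0.84, so such probes leaned upward.

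**Figure D1:**
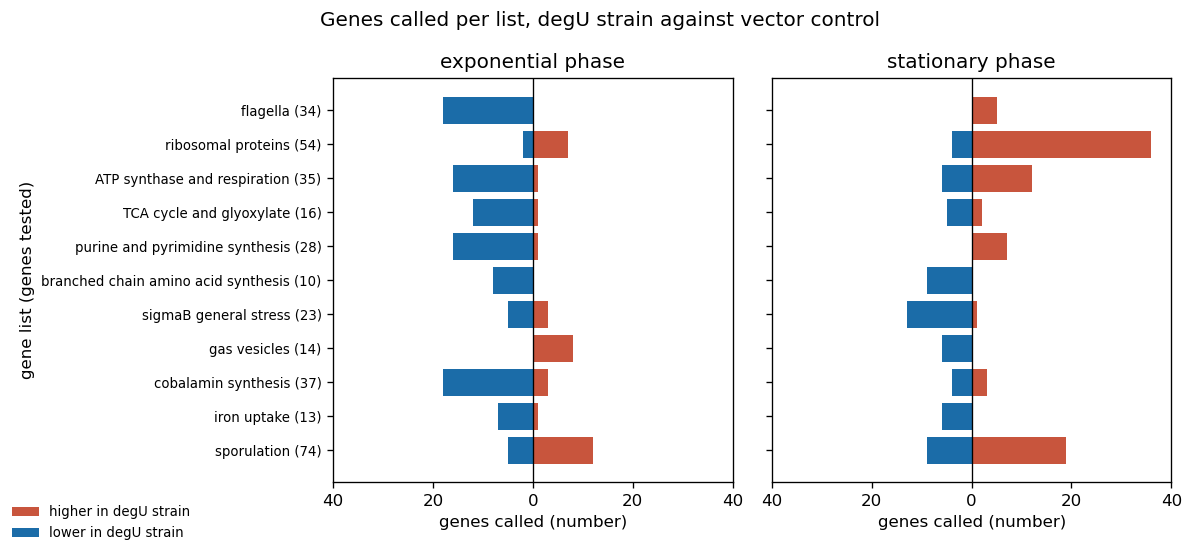
Number of called genes per gene list in exponential (left) and stationary phase (right), with genes higher in the degU strain to the right of 0, genes lower to the left and the number tested in brackets. Ribosomal protein genes were higher for 36 of 54 in stationary phase (7 in exponential phase, and 1 with median centring in place of loess), and 0 of 34 flagellar genes were lower in stationary phase against 18 in exponential phase.

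The stationary comparison asked the same after growth had ceased. BMD_3801 was again at the top, at least 106-fold higher. It was followed by BMD_0992, which encodes a sigma factor (log2 ratio 6.45 ± 0.37, SD, n = 5; adjusted p = 6.03e-10), BMD_0996, a gene for turnover of cyclic di-GMP (5.89 ± 0.40), the AzlC and AzlD family genes BMD_3234 (5.88 ± 0.32) and BMD_3233 (5.28 ± 0.32), the activator gene BMD_3127 (5.85 ± 0.55) and the endopeptidase gene BMD_3881 (5.49 ± 0.79). Among the lowest ratios, the genes with a described product were BMD_1013, which encodes a CsbD-like protein (-6.30 ± 0.62), BMD_1557, which encodes a glucose starvation-inducible protein (-5.28 ± 0.56), ctc (-4.75 ± 0.36), BMD_1538, which encodes a ferritin-like protein (-4.61 ± 0.43), and BMD_2208, a general stress protein gene (-4.42 ± 0.65). Of 4620 genes, 1399 were called, 642 higher and 757 lower, and 328 of them have only a bound. Without background correction the balance turned, with 464 higher and 278 lower.

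Ribosomal protein genes formed the largest group of increases. Of 54, 36 were higher, 4 (rplK, rpsO, rpsA and rplI) were lower and 14 were not called (adjusted p = 4.92e-07; adjusted p = 0.571 with an estimated correlation). The ratio of rplJ was 3.97 ± 0.26 and that of rpsJ 3.87 ± 0.74. In purine and pyrimidine synthesis, 7 of 28 genes were higher, or 6 adjusted over the list alone, and 0 were lower (adjusted p = 0.0202; adjusted p = 0.71 with an estimated correlation). Its largest changes were in the pyrimidine genes pyrH (2.99 ± 0.56) and pyrG (2.58 ± 0.55). Without background correction this list was not past the threshold (adjusted p = 0.0645). In sporulation, 19 of 74 genes were higher, 9 were lower and 46 were not called (adjusted p = 0.0089; adjusted p = 0.64 with an estimated correlation). The phosphorelay gene spo0B stood at 3.22 ± 0.44 and the coat protein gene cotF (BMD_1668) at -3.57 ± 0.53. The sporulation median of 0.385 lay within the range of foreign probes without signal, 0.29 to 0.84. Whether that lean adds to it was not tested.

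The general stress list of sigma-B was lower, with 13 of 23 genes lower, 1 (csbA) higher and 9 not called (adjusted p = 0.00405; adjusted p = 0.571 with an estimated correlation). Besides ctc, its examples were ohrB, organic hydroperoxide resistance (-3.0 ± 0.32), and, chosen after the values were seen, sigB itself (-2.50 ± 0.50). Branched-chain amino acid synthesis was lower again, with 9 of 10 genes lower and 1 not called (adjusted p = 0.000442; adjusted p = 0.571 with an estimated correlation). Both ilvC (at least 13.2-fold) and leuA (at least 9.28-fold) were given as bounds. Gas vesicle genes, higher in exponential phase, were lower here for 6 of 14, with 8 not called (adjusted p = 0.000442; adjusted p = 0.571 with an estimated correlation). The bounds were at least 2.32-fold lower for gvpB and at least 1.4-fold lower for gvpF, whose call was lost without background correction (log2 ratio -0.76). Under that alternative 1 gas vesicle gene was lower, and with processed signals 13 were.

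In the list of DegU targets, 5 of 14 genes were higher, 1 (nprM) was lower and 8 were not called (adjusted p = 0.0872). The protease gene wprA stood at 3.51 ± 0.21 and nprM was at least 9.63-fold lower. The capsule gene capB (BMD_1003) was at least 2.38-fold higher, a call lost without background correction (0.78), and capA (BMD_1005) and capC (BMD_1004) were also higher. The symbol ispA belongs here to a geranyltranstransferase rather than to a protease. It stood at 1.52 ± 0.23, and its call was lost without background correction (0.99) and with median centring (0.87). Of 17 extracellular enzymes, 3 (wprA, ywaD and ggt of BMD_3892) were higher, 4 were lower and 10 were not called (adjusted p = 0.728). Those lower were nprM, the nuclease gene nucB (-2.86 ± 0.57), the amylase gene amyL (at least 4.99-fold) and ggt of BMD_1534. Of 34 flagellar genes, 5 (hag, flgE, fliT, fliS and fliD) were higher and 29 were not called (adjusted p = 0.0955), with hag at 3.27 ± 0.53.

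6 of 28 lists passed the threshold in stationary phase, 0 with an estimated correlation and 25 with fry. Adjusted over the list alone, counts changed only in purine and pyrimidine synthesis. Median centring in place of loess moved the median of all genes from -0.024 to -0.225 and the calls to 513 higher and 1483 lower. With stationary replicates 1 to 3 alone, chosen after the control channels were seen, 1407 genes were called.

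**Figure D2:**
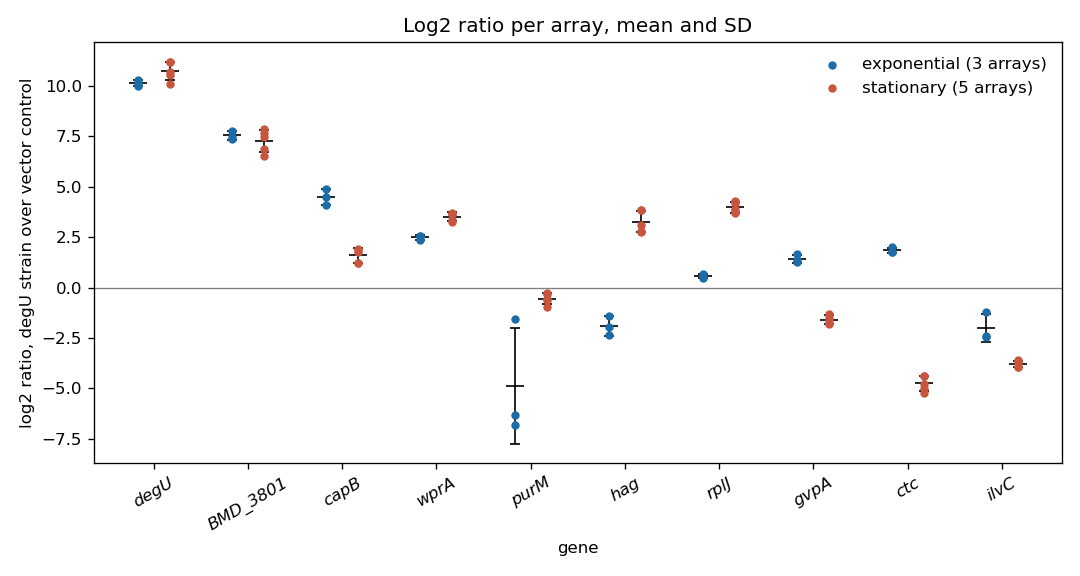
Log2 ratio of the degU strain over the vector control on each array for 10 genes, with 3 exponential and 5 stationary arrays as points and the mean and SD as black bars. The ratio of degU lies near 10 on all arrays, hag and rplJ are higher in stationary phase, ctc and gvpA are lower there, and purM differs between exponential arrays.

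In the authors' deposited table, 1401 genes passed the authors' rule in exponential phase (755 higher, 646 lower) and 1387 in stationary phase (974 higher, 413 lower). The deposited p-values are rounded to 2 decimals, so the rule could not be applied exactly, and with a printed p of 0.01 counted as passing the counts were 1416 and 1396. For 510 and 806 of the genes past the rule the table lists fewer probes than the array holds, and the others could not be checked. The table listed 2046 and 1935 genes, with absolute median ratios of at least 0.8. Across these genes, which are not independent replicates, the log2 ratios of the authors' deposited table and those computed here correlated at r = 0.974 and r = 0.921. Signs were equal for 99.3 % and 96.3 % of them. Of the genes past the authors' rule in the authors' deposited table, 1098 and 966 were also called here in the same direction. The authors' deposited table gives degU at 9.91 and 11.75.

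The effects of degU in both phases were then compared. 313 genes were higher in both phases and 258 were lower in both, a total of 571, where independent lists would share 82.8 and 108.6. 29 genes were lower in exponential and higher in stationary phase, and 64 the reverse, against 92.1 and 97.7 for independent lists. Of the 571 genes, 154 (27 %) also had a called difference between phases. Across all genes the ratios of both phases correlated at r = 0.47 (rho = 0.52). A dye bias specific to a gene would add to this overlap, since dyes were not swapped.

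The difference between phases itself was called for 1176 genes, 558 with a higher ratio in stationary phase and 618 with a lower ratio (487 and 360 without background correction, where the balance turned). The ratio of gabT was higher in stationary phase by 7.51 (SE 0.32, n = 3 and 5; adjusted p = 1.68e-07), that of BMD_1542, a regulator gene of histidine use, by 5.24 (SE 0.345), that of hag by 5.18 (SE 0.31), that of the proline catabolism gene putC by 4.69 (SE 0.27) and that of acoA, acetoin dehydrogenase, by 4.65 (SE 0.63). The ratio of BMD_1013 differed by -7.09 (SE 0.32) and that of ctc by -6.58 (SE 0.20). In purine synthesis, purQ differed by 4.78 (SE 0.65), with 5.86 without exponential replicate 3 and 4.07 without exponential replicate 2, and purE by 4.56 (SE 0.28).

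Of 34 flagellar genes, 24 had a higher ratio in stationary phase and 10 were not called (adjusted p = 1.6e-09; adjusted p = 0.282 with an estimated correlation), with fliS at 2.47 (SE 0.26). In chemotaxis, cheY (1.77, SE 0.12) and cheV (1.08, SE 0.15) were higher and 5 genes were not called (adjusted p = 0.0308; adjusted p = 0.282 with an estimated correlation). This list was not past the threshold without background correction (adjusted p = 0.103), where cheV was not called (0.92), nor was cheV called without exponential replicate 1 (0.97). Respiration was higher for 26 of 35 genes, with 9 not called (adjusted p = 1.6e-09; adjusted p = 0.282 with an estimated correlation). Its largest differences were in the ATP synthase genes atpI (2.57, SE 0.25) and atpB (2.41, SE 0.17). Ribosomal proteins were higher for 30 of 54 genes and lower for 2 (rpsO and rpmE), with rplJ at 3.41 and rpsJ at 3.38 (adjusted p = 1.36e-06; adjusted p = 0.479 with an estimated correlation). Purine and pyrimidine synthesis was higher for 21 of 28 genes, with 7 not called (adjusted p = 2.86e-07; adjusted p = 0.394 with an estimated correlation). Gas vesicle genes were lower for 14 of 14 (adjusted p = 5.15e-09, and 0.282 with an estimated correlation), with gvpB at -3.40 (SE 0.17) and gvpA at -3.01 (SE 0.15). Between phases within the degU strain, 0 of 14 gas vesicle and 0 of 34 flagellar genes were called (list medians -0.196 and 0.004). Within the control, 14 of 14 gas vesicle genes rose and 26 of 34 flagellar genes fell.

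4 further lists were past the threshold for the difference. In the TCA cycle, 10 of 16 genes were higher, 2 (fumC and citA) were lower and 4 were not called (adjusted p = 0.0248; adjusted p = 0.479 with an estimated correlation), with sucC at 2.97 (SE 0.52) and mdh (BMD_3656) at 2.63 (SE 0.30). In the cobalamin list, 11 of 37 genes were higher (adjusted p = 0.000157, and 0.412 with an estimated correlation), with cysI of sulfite reduction at 1.72 and cbiG at 1.62. In the granule list, 5 of 6 genes (phaP, phaQ, phaR, phaB and phaC) were higher (adjusted p = 0.0455; adjusted p = 0.282 with an estimated correlation), with phaQ at 2.02 (SE 0.30) and phaR at 1.51 (SE 0.25). In the iron list, 1 of 13 genes, yfmE (1.02, SE 0.15), was higher (adjusted p = 0.0248; adjusted p = 0.394 with an estimated correlation). The call of yfmE was lost without background correction (0.64) and without exponential replicate 1 (0.88), exponential replicate 2 (0.97) or stationary replicate 5 (0.99). With median centring the TCA, granule and iron lists were not past the threshold (adjusted p = 0.115, 0.115 and 0.13) and phaR was not called (0.90), and with Feature Extraction's processed signals the cobalamin list was not (adjusted p = 0.0798).

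Single capsule and exoenzyme genes differed between phases in both directions, and neither list was past the threshold. The genes capA, capB and capC of BMD_1005, BMD_1003 and BMD_1004 had lower ratios in stationary phase, by -3.08, -2.91 and -2.80, while capC of BMD_1093 had a higher ratio, by 2.81 (SE 0.25). In the list of DegU targets, 4 of 14 genes were higher, 4 were lower and 6 were not called (adjusted p = 0.997). Of 17 extracellular enzymes, 2 (ggt of BMD_1095 and wprA) were higher, 5 were lower and 10 were not called (adjusted p = 0.343). The differences were -3.47 for nucB, -2.27 for ggt of BMD_1534, -2.07 for amyL and 2.57 for ggt of BMD_1095. 10 of 28 lists passed the threshold, 0 with an estimated correlation and 21 with fry. Adjusted over the list alone, counts changed only in sporulation, from 10 to 9 higher.

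The change from exponential to stationary phase within the vector control gave 1212 called genes, 582 higher and 630 lower in stationary phase. BMD_0368, an intracellular protease gene, rose by 6.19 (SE 0.165, n = 3 and 5; adjusted p = 1.35e-08). The glyceraldehyde-3-phosphate dehydrogenase gene gap of BMD_4746 was lowest (-6.40, SE 0.65), followed by gabT (-5.68, SE 0.30), BMD_1542 (-5.37, SE 0.11) and hag (-5.10, SE 0.067). The purine genes purM, purB and purK stood at -5.41, -5.38 and -5.37, and for purM the change was -6.75 without exponential replicate 3 and -4.66 without exponential replicate 2. Of 17 exoenzyme genes, 4 rose (nucB 4.00, amyL 3.26, ggt of BMD_1534 3.12 and nprM 2.95), 2 fell (ggt of BMD_1095 and wprA) and 11 were not called (adjusted p = 0.355). In the list of DegU targets, 5 of 14 genes fell (capA, capB and capC of BMD_1094, BMD_1092 and BMD_1093, wprA, and ispA, which matches by symbol alone), among them capC (-3.05), capB (-2.55) and capA (-2.29), and nprM rose (adjusted p = 0.525). Averaging the near-identical control channels, an alternative chosen after the data were seen, gave 1199 called genes.

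By list, flagellar genes fell in the control for 26 of 34 (adjusted p = 2.42e-11; adjusted p = 0.0601 with an estimated correlation), with motA at least 6.24-fold lower. In chemotaxis, cheR (-1.41) and cheY (-1.39) fell and 5 genes were not called (adjusted p = 0.00225; adjusted p = 0.176 with an estimated correlation), and the call of cheR was lost without background correction (-0.73). Ribosomal proteins fell for 27 of 54 genes and rose for 2 (rpsO and rpsU; adjusted p = 0.00102; adjusted p = 0.587 with an estimated correlation), with rpsJ at -2.65 and rpsC at -2.61. Respiration fell for 23 of 35 genes (adjusted p = 6.82e-09; adjusted p = 0.433 with an estimated correlation), with atpI at -2.56 and atpB at -2.26. Glycolysis and gluconeogenesis fell for 11 of 21 genes (adjusted p = 0.0033; adjusted p = 0.446 with an estimated correlation), with pckA at -5.07. In acetoin and acetate use 9 of 15 genes fell, with acoA at -2.43 and acuC at -2.05, and 2 (alsS and alsD, acetoin synthesis) rose (adjusted p = 0.00941; adjusted p = 0.201 with an estimated correlation). Purine and pyrimidine synthesis fell for 24 of 28 genes (adjusted p = 3.54e-08, and 0.433 with an estimated correlation). The cobalamin list fell for 18 of 37 (adjusted p = 3.52e-05, and 0.446 with an estimated correlation), with cbiF at -2.53 and cbiL at -2.27. Branched-chain synthesis rose for 8 of 10 genes (adjusted p = 0.00127; adjusted p = 0.446 with an estimated correlation), with ilvC at 2.49 and leuB at 2.45, and gas vesicles rose for 14 of 14 (adjusted p = 7.79e-08; adjusted p = 0.433 with an estimated correlation), with gvpB at 2.74 and gvpA at 2.56. 10 of 28 lists passed, 0 with an estimated correlation and 24 with fry, and adjusted over the list alone counts changed only in autolysis, from 3 to 2 lower.

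Within the degU strain, 554 genes changed between phases, 214 higher and 340 lower in stationary phase. Without background correction the balance turned, with 241 higher and 206 lower. BMD_0996 rose by 4.23 (SE 0.19, n = 3 and 5; adjusted p = 5.95e-08), BMD_0992 by 3.73 (SE 0.17) and the extracellular ribonuclease gene bsn by 3.27 (SE 0.14). The gene gap of BMD_4746 fell by 3.18 (SE 0.24), the transporter genes BMD_1774 and BMD_0833 stood at -2.72 and -2.63, and the amylase gene BMD_2470 was at least 4.13-fold lower. The capsule genes capA, capB and capC of BMD_1005, BMD_1003 and BMD_1004 stood at -2.64, -2.50 and -2.33. Of the calls, 109 have only a bound, and 18 genes were not well above background in either phase, so no fold is given for them; nprM, amyL, ilvD and ilvH are among these. Fewer probes were well above background in this channel in stationary phase, which may limit what could be called, though this was not tested.

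By list, glycolysis fell in the degU strain for 10 of 21 genes (adjusted p = 3.43e-06; adjusted p = 0.448 with an estimated correlation), with gpmI at -1.73. Purine and pyrimidine synthesis fell for 14 of 28 (adjusted p = 3.43e-06; adjusted p = 0.448 with an estimated correlation), with pyrC at -2.32 and pyrAB at least 3.14-fold lower. In sporulation, 6 of 74 genes rose and 3 (spo0M of BMD_3021, sleB of BMD_3220 and spoIIR) fell (adjusted p = 0.0126; adjusted p = 0.448 with an estimated correlation), with the spore protein gene sspC at 2.57 (BMD_0487) and 2.04 (BMD_0561). This list was not past the threshold without background correction (adjusted p = 0.0641) or with processed signals (adjusted p = 0.057). In branched-chain synthesis, 4 of 10 genes (ilvA, ilvB, ilvD and ilvH) were called higher (adjusted p = 0.000785; adjusted p = 0.448 with an estimated correlation), against 9 without background correction and 0 with median centring or scale normalization. In the TCA cycle, fumC rose by 1.13 and mdh (BMD_3656) was at least 1.76-fold higher (adjusted p = 0.0279; adjusted p = 0.549 with an estimated correlation); with median centring and scale normalization this list was not past the threshold (adjusted p = 0.0647 and 0.375). In the cobalamin list, cbiF (-1.19) and cbiL fell and cysP (1.16) rose (adjusted p = 0.0248, and 0.549 with an estimated correlation). Of 54 ribosomal protein genes 0 were called, with a list median of 0.60 (adjusted p = 4e-05; adjusted p = 0.448 with an estimated correlation), and the direction turned under scale normalization (0 higher, 4 lower, adjusted p = 0.704). Without background correction 19 ribosomal genes were called higher, and with processed signals 16 were higher and 2 lower. The protease gene htrA fell by 1.14.

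Several single calls of this comparison rested on the processing. Calls of mdh (0.57) and cbiF (-0.99) were lost without background correction. With median centring those of fumC (0.60), cysP (0.79) and htrA (-0.99) were lost, as was that of htrA with the median over probes (-0.998). Calls of ilvD, ilvH, nprM and amyL, dim in both phases, were also lost with median centring, those of ilvD, ilvH and nprM with scale normalization, and that of ilvD without exponential replicate 1 or exponential replicate 2. The call of nprM was lost without exponential replicate 1 or stationary replicate 4. The call of cysP was also lost without exponential replicate 2 (0.98) or exponential replicate 3 (0.97). With median centring the calls stood at 96 higher and 340 lower.

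The growth phase changes of both strains correlated across genes at r = 0.34 (rho = 0.39). 926 genes were called in the control alone, 268 in the degU strain alone, 248 in both in the same direction, where independent lists would share 73.3, and 38 in opposite directions. Both strains were measured on the same spots, so an effect common to both channels of a spot may add to this overlap and correlation. Genes that changed between phases in the control often had the opposite degU effect in stationary phase. 351 genes that rose in the control had a lower ratio in stationary phase, where independent lists would share 95.4, and 186 genes that fell had a higher ratio, against 87.5. In the same direction there were 28 genes higher in both and 21 lower in both, against 80.9 and 103.2. The stationary control channels enter both values with opposite sign, which independent lists leave out, and part of the opposite counts may come from them. Data simulated with no effects gave 0 genes in each of these groups, which leaves out real effects. With the degU effect from stationary arrays 2 to 4 and the growth change from arrays 1 and 5, the counts were 330 and 187 in opposite directions and 42 and 59 in the same direction. The reverse choice of arrays gave 369, 183, 21 and 14. This separation was chosen after the results were seen.

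**Figure D3:**
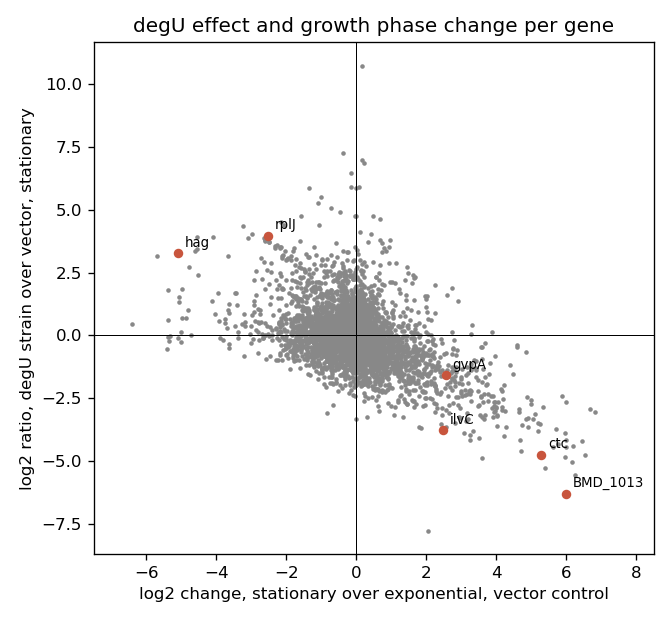
Log2 ratio of the degU strain over the vector control in stationary phase (vertical) against the log2 change from exponential to stationary phase in the vector control (horizontal), with 1 point per gene for 4620 genes and named genes in red. Points fall from upper left to lower right, with hag and rplJ at the upper left and ctc, BMD_1013 and gvpA at the lower right, and the stationary control channels enter both axes.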

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

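Tests of a compressed Cy3 scale and of the purine genes were chosen only after the results were seen, as were the arrays used to separate the shared control channels and the resampling of genes behind the spread of the guanine correlation.

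The degU effect differed between exponential and stationary phase for 1176 genes. 1 of 56 splits of the 8 arrays, the real one, gave as many genes (highest other 0), so chance can be excluded for this count if the arrays are independent, which the near-identical control channels leave unsure. For the 10 lists with a difference, 15 of 56 splits gave as many (highest other 13), so chance cannot be excluded. The list medians of the difference were 2.36 for purine and pyrimidine synthesis, 1.49 for ATP synthase and respiration, 1.40 for the TCA cycle, 1.37 for flagella, 1.34 for polyhydroxyalkanoate granules, 1.13 for ribosomal proteins, 0.84 for chemotaxis, 0.73 for iron uptake, 0.70 for cobalamin synthesis and -2.02 for gas vesicles.

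Of 108 genes named, 86 had a degU effect that differed between phases in limma's test of the difference itself. Many of them were named for a call in that same test or for a large change in a single phase. The selection thus raised this count, and over all 4620 genes tested the share called was 25.5 % (1176 genes). Ratios were higher in stationary phase for gabT 7.51, BMD_1542 5.24, hag 5.18, purQ 4.78, putC 4.69, acoA 4.65, purE 4.56, purN 4.54, purH 4.44, purM 4.34, purD 4.33, purK 4.32, purS 4.24 and BMD_0996 4.14. Further upward differences were purF 4.13, purC 4.03, hisD (BMD_1657) 4.02, BMD_0992 3.88, rplJ 3.41, rpsJ 3.38, sucC 2.97, capC (BMD_1093) 2.81, pyrG 2.80, mdh (BMD_3656) 2.63, BMD_3127 2.59, ggt (BMD_1095) 2.57, atpI 2.57 and fliS 2.47. Others were motA 2.46, atpB 2.41, BMD_3881 2.28, acuA 2.27, phaQ 2.02, fliM 1.92, BMD_3234 1.86, ctaC 1.82, cheY 1.77, cysI 1.72, cbiG 1.62, spo0B 1.60, oppC 1.59 and BMD_3233 1.54. Upward differences were also found for phaR 1.51, BMD_2264 1.48, ctaE 1.27, rpsB 1.19, odhB 1.19, cysC 1.13, pyrH 1.13, cheV 1.08, wprA 1.02, yfmE 1.02, lytF (BMD_3978) 1.01 and icd 1.01. Ratios were lower in stationary phase for BMD_1013 -7.09, ctc -6.58, BMD_2208 -6.14, BMD_1557 -5.06, BMD_1538 -4.99, cotF (BMD_1668) -4.41, ohrB -4.32, nucB -3.47, gvpB -3.40, nin -3.30, capA (BMD_1005) -3.08 and gvpA -3.01. Further downward differences were capB (BMD_1003) -2.91, capC (BMD_1004) -2.80, pstS -2.65, gltB -2.51, clpP (BMD_5044) -2.32, gvpF -2.30, ggt (BMD_1534) -2.27, spo0M (BMD_4015) -2.08, amyL -2.07, BMD_2936 -2.01, sleB (BMD_3220) -2.01 and BMD_0195 -1.87. Downward differences were also found for nprM -1.86, clpE -1.79, gvpP -1.78, ilvC -1.76, gap (BMD_5038) -1.63, leuA -1.45, BMD_0917 -1.25 and ywaD -1.23. The size of these purine differences moved with single exponential arrays: purN, purM, purH, purQ, purD, purF, purS and purC stood at 6.16, 5.99, 5.94, 5.86, 5.78, 5.54, 5.31 and 4.83 without exponential replicate 3, and at 3.64, 3.38, 3.65, 4.07, 3.60, 3.36, 3.48 and 3.42 without exponential replicate 2. Without exponential replicate 1, purN, purM, purH, purD and purF stood at 3.82, 3.64, 3.73, 3.62 and 3.49. Without single exponential arrays the calls of lytF, cheV and yfmE (replicate 1, 0.91, 0.97 and 0.88), of wprA, lytF, icd, cysC and yfmE (replicate 2, 0.95, 0.99, 0.89, 0.76 and 0.97) and of leuA (replicate 3, -0.88) were lost. Without single stationary arrays those of lytF, rpsB, icd, cysC and pyrH (replicate 1, 0.93, 0.96, 0.97, 0.94 and 0.91), of wprA (0.97, 0.99 and 0.99 without replicates 2, 3 and 5) and of lytF, icd and yfmE (replicate 5, 0.93, 0.80 and 0.99) were lost.

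For 49 named genes the 5 stationary arrays were tested for a single array far from the others, and 0 genes had one. Among the 18 probes of other sequences, the probe SPYocH had signal above background on 8 arrays in both channels (medians 7858 in Cy3 and 16567 in Cy5), with a mean log2 ratio of 0.76 (SD 0.48).

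In stationary phase the degU effect ran opposite to the growth phase change of the control, with a covariance across genes of -0.748 (r = -0.49). Noise of the shared control channels is argued against as the whole cause: with the degU effect from stationary arrays 2 to 4 and the growth change from arrays 1 and 5, the covariance was -0.629, a ratio of 0.841 to that with all arrays, the reverse choice of arrays gave -0.84, and simulated data with no effects gave -0.0113 (r = -0.44). A compressed Cy3 scale stays open, since 5.78 % of genes called in the control changed at least as much in Cy3 in the same direction, between the bounds set for and against it. These genes were selected for a change in the control, which lowers that share. Over genes called in either channel, 347 of 1480 (23.4 %) changed more in Cy3, whatever the direction, a share for which no bounds were set. An effect of degU itself stays open and was not tested.

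571 genes were called in both phases in the same direction. A dye bias of single probes is argued against, since 91.5 % of the genes had every probe past the limit in their direction in both phases, 73.4 percentage points above shuffled probes (18.1 %). The correlation of the log2 ratio with the guanine content of probes was r = 0.0859 (rho = 0.11, 13630 probes), under the bound of 0.1 by more than its spread (SD 0.00868, 100 resamples of genes), which argues against a bias that follows guanine as the whole cause, though the rank correlation lay above that bound. A dye bias of whole transcripts was not tested and stays open, since dyes were not swapped, and so does an effect of degU in both phases. 1 of 100 drawn sign flips of the arrays, the real one, gave 571 genes (highest other 0). Flips of part of a phase cancel its mean and left at most 0 calls in exponential and 1 in stationary phase. An overlap near 0 was thus fixed in advance, so this test cannot decide whether the phases overlap by chance.

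Ratios of purine genes differed among exponential arrays, with purM at -6.29, -6.80 and -1.58. A defect of the spots or of the array is argued against: over 12 pur genes with consecutive locus tags the Cy3 shift of array 3 was 0.557 and the Cy5 shift -3.109, a ratio of 0.179 in size, and 0 of 36 spots carried an outlier mark. A state of the control culture on that array stays open, and no biological explanation was tested.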

How the results depend on the processing

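Stationary replicates 1 to 3 alone and averaged control channels were chosen only after the data were seen. The share of Cy3 probes above background, 23.9 % to 40.5 % in stationary phase, may limit what could be called there, though this was not tested.

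For degU against the control, calls ranged over the alternatives from 974 to 3287 in exponential phase and from 742 to 3716 in stationary phase. For the difference they ranged from 847 to 2709, for growth in the control from 970 to 3081 and in the degU strain from 436 to 2352. The degU log2 ratio ranged from 9.52 to 11.74 in exponential and from 9.88 to 12.03 in stationary phase. Of the values of named genes under the alternatives, 4284 kept their direction and side of the threshold, 37 fell short of it, 3 passed it and 5 reversed. Many of the values kept could hardly move. Leaving out an array of a phase keeps the log2 ratios of the other phase, and other variance models or fits on a single phase keep the log2 ratios as well. Sizes were less stable: of 197 values per alternative, 117 moved by over 1.5-fold with median centring, 112 with processed signals, 68 without background correction, 14 with scale normalization, 10 with an offset of 0 and at most 9 under any other. The balance of higher and lower calls turned without background correction in exponential phase (496, 478), in stationary phase, for the difference (487, 360) and for growth in the degU strain (241, 206). It also turned in the table deposited by the authors in exponential (755, 646) and stationary phase (974, 413), and without the size limit for the difference (1439, 1270).

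The following counts lay outside 1.5 times the reported count, and the cause was not tested unless stated. No background correction gave 742 calls in stationary phase (464 higher, 278 lower) and 335 genes called in both phases. Feature Extraction's processed signals gave 2185, 2407, 2059, 1840 and 1424 calls for exponential, stationary, difference, growth in the control and growth in the degU strain, and 1205 in both phases. Median centring gave 903 genes in both phases and 10 lists in stationary phase. Without the size limit, by construction, calls rose to 3287, 3716, 2709, 3081 and 2352, with 2233 in both phases. Of the genes past the size limit, 0 failed the adjusted p in exponential or in stationary phase. The size limit alone therefore set the counts of degU against the control. Lists past the threshold for exponential, stationary, difference and growth in the control numbered 0, 0, 0 and 0 with camera's estimated correlation and 25, 25, 21 and 24 with fry.

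The degS difference reversed to -0.02 (-0.023) without background correction, -0.259 with processed signals and -0.019 without exponential replicate 3 (0.172 without exponential replicate 1). The degU difference reversed to -1.79 (-1.793) with scale normalization and -0.203 with the median over probes. It passed the threshold at 1.21 with processed signals, and degS passed it with median centring at 1.02 and 1.10 in the exponential and stationary phases; the cause was not tested.

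Leaving out 1 array at a time gave 1171 to 1362 calls in exponential phase, 1377 to 1412 in stationary phase, 1128 to 1202 for the difference, 1166 to 1253 for growth in the control, 531 to 584 in the degU strain and 545 to 601 in both phases. Lists numbered 10 to 11, 6 to 6, 10 to 14 and 10 to 11. Stationary replicates 1 to 3 alone gave 1407 calls in stationary phase and 575 in both. With the replicate block, 1170, 1203 and 546 genes were called for the difference and both growth changes. Deviations of same-numbered arrays from the means of their phases correlated at -0.13 to 0.12, over log2 ratios and both single channels. These values gave no sign that the numbers pair the arrays.

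As for other splits, in exponential phase 1 of 4 sign flips gave 1259 genes (highest other 0), too few flips for a share under 0.05. In stationary phase 1 of 16 gave 1399 genes (highest other 1), also too few. As many lists as reported came from 2 of 4 flips in exponential phase (10 lists, highest other 10). In stationary phase they came from 12 of 16 flips (6 lists, highest other 11), so chance cannot be excluded for either list count. For growth in the control, 1 of 56 splits gave 1212 genes (highest other 11), which excludes chance only if the 5 stationary controls are independent: with near-identical channels counted once, 3 against 3 controls make too few splits. 22 of 56 gave 10 lists (highest other 15), so chance cannot be excluded there. For growth in the degU strain 1 of 56 gave 554 genes (highest other 13), which excludes chance only if the arrays are independent. The Cy3 values were normalized together with the control channels, so the near-identical control channels leave that unsure.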

Other observations

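No tests were added here after the results were seen. The lists not past the threshold in a phase, except phosphate starvation in stationary phase, held called genes of their own. They are given here as values with the SD over arrays, higher and lower meaning the degU strain against the control.

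In exponential phase, secretion had 6 genes higher and 4 lower of 22 (adjusted p = 0.74), with the signal peptidase gene sipM at 2.68 ± 0.26 (1 higher and 6 lower with median centring). Heat shock had 7 higher and 4 lower of 24 (adjusted p = 0.36), with clpE at 3.15 ± 0.67. Sigma-B stress had 3 higher (ctc, ohrB and dps) and 5 lower of 23 (adjusted p = 0.489), with the kinase gene rsbT at -1.90 ± 0.19. Capsule genes had 5 higher and 4 lower of 10 (adjusted p = 0.785). Competence had 2 higher (cinA and comFA) and 1 lower of 23 (adjusted p = 0.629), with ssbB at least 4.15-fold lower. Autolysis had 1 higher (cwlD) and 4 lower of 11 (adjusted p = 0.812; median 0.28, mean -0.56), with lytF (BMD_3978) at -2.81 ± 0.24. SOS had 2 higher (yneA and yneB) and 1 lower of 8 (adjusted p = 0.406), with lexA at -1.81 ± 0.09.

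Carbon and nitrogen lists in exponential phase were mixed. Glycolysis had 1 higher (pdhA) and 6 lower of 21 (adjusted p = 0.0751), with fba (BMD_5161) at -3.01 ± 0.15. Xylose and pentose use had 2 higher and 1 lower (xylR) of 17 (adjusted p = 0.257), with araA at 2.69 ± 0.18. Carbohydrate use had 6 higher and 2 lower (galK and galT) of 34 (adjusted p = 0.442), with the glycerol uptake gene glpF at 2.50 ± 0.40 (9 higher and 11 lower with processed signals). Acetoin and acetate had 1 higher (ackA) and 8 lower of 15 (adjusted p = 0.0561), with acuA at -1.91 ± 0.11. Histidine, tryptophan and arginine synthesis had 1 higher (argE) and 3 lower of 26 (adjusted p = 0.442), with hisD (BMD_1657) at -1.51 ± 0.44. Nitrogen and peptide use had 8 higher and 12 lower of 51 (adjusted p = 0.629), with oppC at -2.70 ± 0.28. Phosphate starvation had 4 higher and 1 lower (phoH) of 12 (adjusted p = 0.426), with pstS at 1.70 ± 0.29, a call lost without exponential replicate 1 (1.61, adjusted p = 0.082) or exponential replicate 2 (1.63, adjusted p = 0.0803). Polyhydroxyalkanoate granules had 3 lower of 6 (phaB, phaC and phaZ; adjusted p = 0.113), with phaZ at least 2.35-fold lower, a call lost without background correction (-0.95).

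In stationary phase, respiration had 12 higher and 6 lower of 35 (adjusted p = 0.643), with atpI at 2.58 ± 0.44; with median centring 1 was higher and 18 were lower, with a median of -1.47. The TCA cycle had 2 higher (mdh of BMD_3656 and sucC) and 5 lower of 16 (adjusted p = 0.277), with mdh (BMD_4754) at -2.59 ± 0.33. Glycolysis had 3 higher and 7 lower of 21 (adjusted p = 0.784; median 0.12, mean -0.34), with gap (BMD_5038) at -2.81 ± 0.29. Xylose and pentose use had 4 higher and 1 lower of 17 (adjusted p = 0.139), with araD at 2.96 ± 0.30. Carbohydrate use had 8 higher and 2 lower of 34 (adjusted p = 0.314), with glpF at 3.35 ± 0.35 (10 higher and 11 lower with processed signals). Acetoin and acetate had 5 higher and 2 lower (alsS and alsD) of 15 (adjusted p = 0.302), with acoA at 2.88 ± 1.30. Nitrogen and peptide use had 4 higher and 15 lower of 51 (adjusted p = 0.0967), with gltB at least 6.88-fold lower (7 lower without background correction, 28 with median centring). Phosphate starvation had 0 called of 12 in limma's test (adjusted p = 0.643), and 6 lower with median centring.

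Also in stationary phase, secretion had 7 higher and 3 lower of 22 (adjusted p = 0.867; median -0.21, mean 0.28), with sipM at 2.79 ± 0.33; with median centring 3 were higher and 8 lower. Heat shock had 5 higher and 4 lower of 24 (adjusted p = 0.606), with clpP (BMD_5044) at -3.62 ± 0.47; with median centring 1 was higher and 14 were lower. Chemotaxis had 1 higher of 7, cheR at 1.5 ± 0.27 (adjusted p = 0.111), a call lost without background correction (0.75). Competence had 1 higher (comFA) and 5 lower of 23 (adjusted p = 0.221), with nin at -2.64 ± 0.52. Capsule genes had 4 higher of 10 (capA, capB, capC and capD; adjusted p = 0.139). Autolysis had 3 higher and 2 lower of 11 (adjusted p = 0.302), with lytF (BMD_3978) at -1.79 ± 0.32. Histidine, tryptophan and arginine synthesis had 3 higher and 9 lower of 26 (adjusted p = 0.314), with hisD (BMD_1657) at 2.52 ± 0.66, a call lost with median centring (0.92); without background correction 1 was higher and 0 were lower. Iron uptake had 6 lower of 13 (adjusted p = 0.314), with sufS of iron-sulfur assembly at -1.96 ± 0.32. Granules had 1 higher of 6, phaQ at 1.81 ± 0.56 (adjusted p = 0.488), a call lost with median centring (0.19). The cobalamin list had 3 higher and 4 lower of 37 (adjusted p = 0.488), with cysK of cysteine synthesis at -3.26 ± 0.93 (0 higher and 24 lower with median centring). SOS had 1 lower of 8, lexA at -1.95 ± 0.30 (adjusted p = 0.643).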
